A study of Mus musculus with 40 samples.

How the data were processed

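Gene expression had been measured on 40 Affymetrix mouse expression arrays, 12 of sorted bone marrow pre-B cells and 28 of lymph node leukemia cells selected with beads. Per the labels, RNA was isolated with an RNeasy kit, amplified with Message Amp II, labelled with biotin and hybridised. The deposited values were linear probe set intensities, all positive. How the authors summarised, background-corrected and normalized them is not given in the sources used here. Groups and replicate numbers came from the sample titles, cell isolation and pooling from the sample descriptions, and the scale of the values from the table itself. WT replicates 1 and 2 were pools of 3 mice.

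Array medians differed by up to 1.45-fold, above a limit of 1.2-fold set beforehand, so each array was scaled to one common median. Intensities under a floor of 16 were set to it, which touched between 3.89% and 4.99% of values per array, and log2 was taken. Of 45101 probe sets 34958 named 1 gene, 932 named several and 9211 named none, and the last 2 kinds were left out of the gene comparisons. For 34754 probe sets the symbol was found in the RefSeq table of GRCm38.p6, the source of all coordinates. The probe set with the highest mean over all arrays stood for each of 18194 genes. A gene was tested when its mean in at least 1 group of the fit exceeded the 40th percentile of all values, a log2 value of 6.79 (intensity 111). The number of arrays limits the precision.

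Comparisons used limma 3.58.1 in R 4.3.3, with lmFit on group means, eBayes with trend and a Benjamini-Hochberg adjusted p under 0.05. The 12 pre-B arrays shared a fit for the pre-B comparisons, the 28 leukemia arrays for the second mutations, and all 40 arrays for comparisons across cell sources. The leukemias as a whole were the unweighted mean of 6 genotype means. The interaction was the xid effect in leukemia minus the xid effect in pre-B cells. Groups were said not to overlap when every array of one lay above or below every array of the other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

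The comparisons, tests, filters, gene lists, rule for named genes and most alternatives were fixed before the data were examined. By that rule the 10 largest rises and 10 largest falls past the threshold were named in each of the 4 comparisons with pre-B cells, and 5 and 5 elsewhere. Their mean in the higher group had to exceed the median of all values, a log2 value of 7.29. Clone and predicted names, sex-linked genes and immunoglobulin or T cell receptor segments were passed over. The targeted genes Stat5b, Stat5a, Btk, Prkcb, Blnk, Ebf1, Rag2 and Pax5, and up to 4 members of each list with the smallest p, could be named in any comparison.

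The 20 lists covered STAT5 target genes, pre-B cell receptor components and signalling, B-lineage transcription factors, B cell maturation genes, progenitor and pro-B genes, NF-kappaB pathway genes, proliferation genes, MYC-linked biosynthesis genes, apoptosis and cell-cycle inhibitor genes, and cytokine receptor and kinase genes. The others were T cell markers, NK cell and cytotoxic markers, neutrophil and myeloid markers, erythroid markers, plasma cell markers, plasmacytoid and dendritic cell markers, stromal and endothelial markers, immediate-early and stress genes, mitochondrial respiration genes and sex-linked genes. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of one comparison, and again with an estimated correlation, under which no list was called. Member counts were also adjusted over the list alone. Camera sets a list against the other tested genes, so its direction can differ from the sign of the list's median.

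The alternatives fixed in this way were quantile normalization, no filter and a 60th percentile filter, the mean or the most variable probe set of a gene, only the compared groups or all arrays in the fit, and eBayes without trend or robust. Further ones were array weights, replicate number as a block, Y-linked expression as a covariate, a floor of 64, omission of each replicate and of the pooled arrays, and other weights of the leukemia genotypes. Added after the data were seen were each second mutation against the mean of the other 4, hybridisation controls (18 probe sets) as a covariate, and omission of the library labelled Rag2-/- replicate 3. Random steps used seed 1. The effect of shared controls came from 20 simulations, chosen after the data were seen. In them all arrays were drawn independently around one mean with the residual spread of each gene.

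The pipeline was tested on simulated data with 200 changed genes per comparison. Of those changed by 1 on the log2 scale it recovered 98% for Stat5b-CA and 98% for Xid pre-B cells, 86% for Stat5b-CA leukemia against pre-B cells and 92% for the leukemias against WT. For the second mutations it recovered 78% for Prkcb-/-, 84% for xid, 81% for Blnk+/-, 81% for Ebf1+/- and 74% for Rag2-/-, and for the interaction 63%. Of those changed by 2 it recovered between 96% and 100% in every comparison, with 7 to 17 false calls. These percentages came from one simulated draw per comparison, and an earlier draw with the genes in another order moved several of them by a few points. They need not hold for the measured arrays. There, omitting single arrays gave 72 to 484 genes for Stat5b-CA and 28 to 397 for Xid pre-B cells.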

Results

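Gene expression was measured on 40 microarrays, 1 RNA sample per array, in mice with Stat5b-CA, a transgene for a constitutively active form of the transcription factor STAT5b, and in controls. The 12 pre-B cell arrays came from bone marrow cells sorted as B220+ CD19+ CD43- IgM- and comprised WT (n = 5, of which 2 were pools of 3 mice), Stat5b-CA (n = 4) and Xid (n = 3). Xid mice carry xid, a point mutation of Btk, a kinase that acts downstream of the pre-B cell receptor. The 28 leukemia arrays came from lymph node cells selected with beads for B220 and CD19. They comprised Stat5b-CA alone (n = 6) and Stat5b-CA combined with Prkcb-/- (n = 4), xid (n = 5), Blnk+/- (n = 5), Ebf1+/- (n = 5) or Rag2-/- (n = 3). Prkcb encodes protein kinase C beta, Blnk an adaptor of pre-B cell receptor signalling, Ebf1 a transcription factor that specifies the B lineage, and Rag2 a subunit of the recombinase that assembles immunoglobulin genes.

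The deposited median intensity lay between 192.4 and 206.5 on the 6 Stat5b-CA leukemia arrays and between 142.7 and 161.5 on the other 34. The ratio of these medians was 1.28-fold, 0.35 on the log2 scale, and every change below is relative to arrays scaled to one median. Changes are log2 differences with the standard error (SE) of the limma contrast. Unless a gene has its own number of arrays beside it, every array of the first-named group lay on the stated side of the other group's mean. The number of arrays limits the precision of all values.

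On the GRCm38.p6 assembly Stat5b lies on chromosome 11 from 100780731 to 100859004, Btk on chromosome X from 134542334 to 134583628 and Prkcb on chromosome 7 from 122289104 to 122634402. Blnk lies on chromosome 19 from 40928927 to 40994221, Ebf1 on chromosome 11 from 44618100 to 45008096 and Rag2 on chromosome 2 from 101624712 to 101632528. In the pre-B groups the mean log2 intensity of Prkcb, Blnk, Ebf1 and Rag2 showed no change past the threshold in Stat5b-CA or Xid cells.

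**Figure D1:**
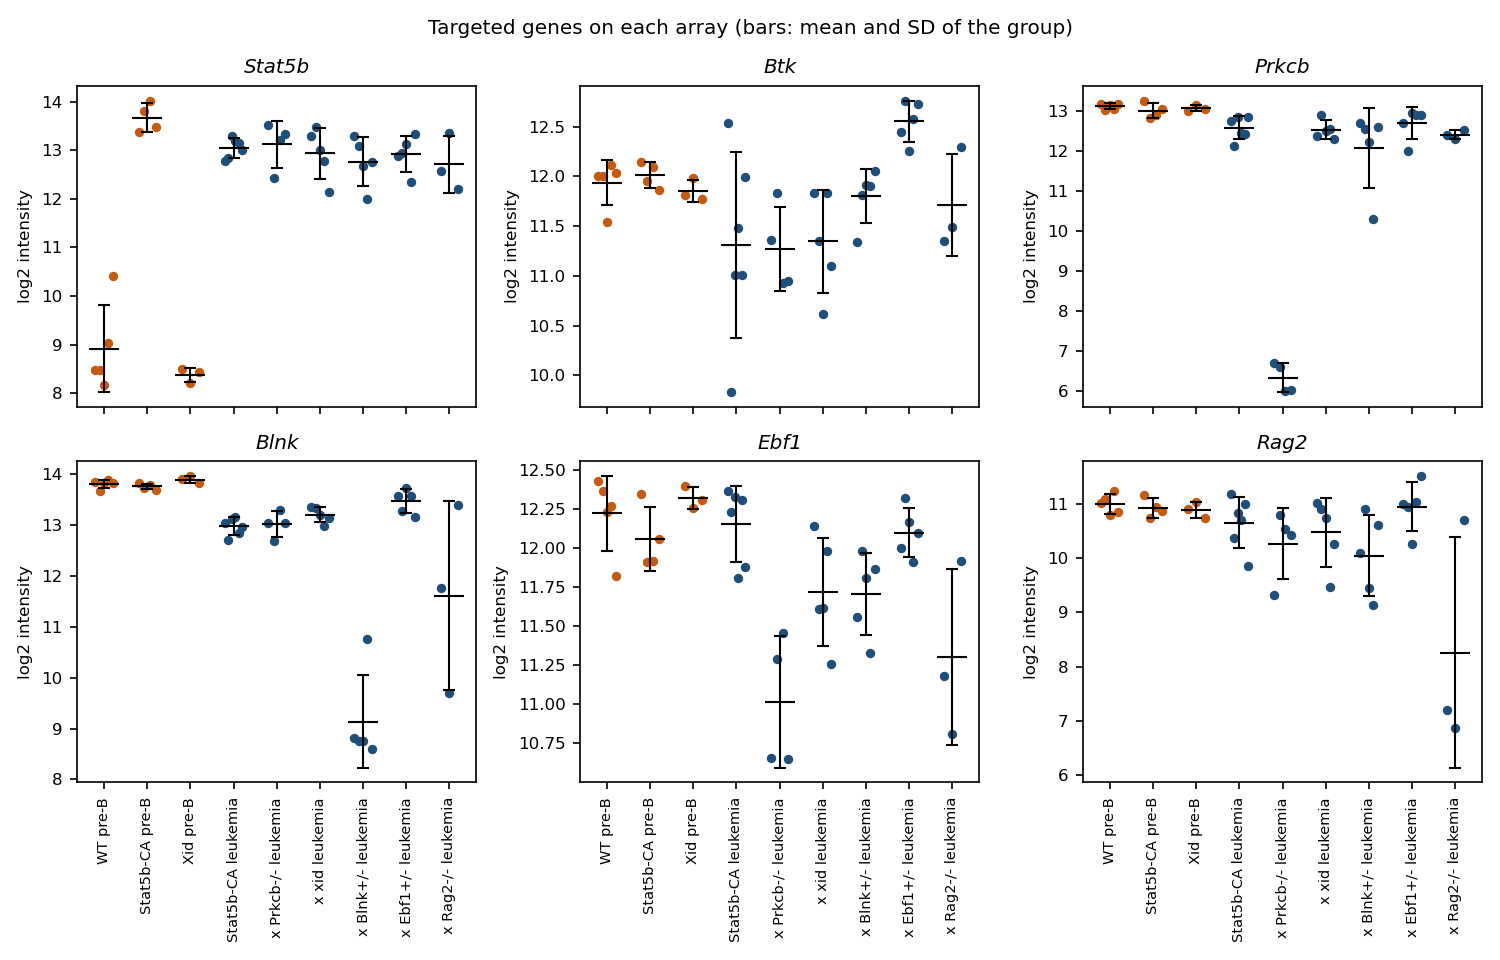
Log2 intensity of 6 targeted genes (vertical axes) on every array, by group (horizontal axis); points are arrays, orange for pre-B and blue for leukemia, and black bars are the group mean and SD. Prkcb averaged 6.32 in the Prkcb-/- leukemias and 12.58 in the Stat5b-CA leukemias, and 1 of the 3 arrays labelled Rag2-/- had a Rag2 value of 10.7.

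The comparison of Stat5b-CA with WT pre-B cells asked what active STAT5b does before leukemia. Stat5b itself rose by 4.75 ± 0.33 (SE, n = 4 against 5), from a mean of 8.91 to 13.66, a 27.0-fold difference with an adjusted p of 6.58e-07. A second Stat5b probe set read -0.43, so the rise concerned the part of the message covered by the first. Socs2, a feedback inhibitor induced by STAT5, rose by 2.05 ± 0.23 and Ccnd2, the cell-cycle regulator cyclin D2, by 2.04 ± 0.24. Crhbp, which encodes a binding protein for corticotropin-releasing hormone, rose by 4.15 ± 0.38, Bpnt1, a phosphatase, by 2.82 ± 0.16 and Gbp7, an interferon-inducible GTPase, by 2.44 ± 0.19. Pcdh9 rose by 2.33 ± 0.16, Myl10 by 2.26 ± 0.32, Sema4a, a semaphorin, by 2.19 ± 0.17, Lmo7 by 2.16 ± 0.20 and Myh10, a nonmuscle myosin, by 2.11 ± 0.23. The granule proteins S100a8 and S100a9 were lower at -2.14 ± 0.40 and -1.97 ± 0.42. Btla, an inhibitory lymphocyte receptor, was lower at -1.25 ± 0.23, Hdac9, a histone deacetylase, at -1.22 ± 0.18, Clcf1, a cytokine, at -1.04 ± 0.20, Trib2 at -1.02 ± 0.15, Ccnk at -0.97 ± 0.21, Dtx1, a regulator of Notch signalling, at -0.97 ± 0.19, Fam169b at -0.88 ± 0.11 and Gpr12 at -0.87 ± 0.15. Their adjusted p values ran from 1.82e-07 for Bpnt1 to 0.0257 for S100a9 and Ccnk.

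By list in Stat5b-CA pre-B cells, 3 of 18 STAT5 target genes rose, 0 fell and 15 did not pass, with Socs3 rising by 0.56 ± 0.12 beside Socs2 and Ccnd2 (6 higher and 2 lower adjusted over the list alone). Camera gave this list an FDR of 0.00138 upward, with a median of 0.0451 and a mean of 0.281, but an adjusted p = 0.36 with an estimated correlation. Of 18 NF-kappaB pathway genes 1 fell, the subunit Relb, at -0.60 ± 0.13, and 5 were lower adjusted over the list alone (camera FDR 0.0223, adjusted p = 0.981 with an estimated correlation). Among 18 neutrophil and myeloid markers 3 fell, S100a8, S100a9 and Ngp, the last at -0.79 ± 0.19. Camera gave an FDR of 0.0192 and an adjusted p = 0.981 with an estimated correlation, with 3 lower adjusted over the list alone. No call was made for the B cell maturation genes, of which Cxcr5, a chemokine receptor, rose by 1.56 ± 0.18 while 9 of 22 were lower adjusted over the list alone (camera FDR 0.06). The B-lineage transcription factors had 1 rise and 2 falls among 22 genes, Erg at 1.40 ± 0.23, Irf8 at -0.58 ± 0.13 and Spib at -0.44 ± 0.09. In the pre-B cell receptor list Vpreb1, a surrogate light chain component, was the 1 gene of 21 to rise, by 0.76 ± 0.10. Median and mean of that list were -0.0782 and -0.0603 where the test pointed upward (FDR 0.956). Of 20 cytokine receptor and kinase genes 3 rose and 2 fell, with Csf2rb, a receptor subunit for interleukin 3, at 1.53 ± 0.18, Csf2rb2 at 1.18 ± 0.13 and Ptpn6, a phosphatase, at -0.52 ± 0.11. The progenitor receptor Kit rose by 0.87 ± 0.15. None of 27 proliferation genes passed with limma, and camera gave that list an FDR of 0.198.

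The limma count for Stat5b-CA against WT pre-B cells was 221 of 13256 genes, 102 higher and 119 lower, with 39 higher and 6 lower by at least 2-fold and 2339 at an unadjusted p under 0.05. Groups did not overlap for 201 of these and for 847 genes in all, 6.39% where chance gives 1.59%. After quantile normalization the count was 216 with 59.3% higher in place of 46.2%, so the balance of rises and falls is not settled. Single arrays decided the count: it was 112 without WT replicate 1, 484 without Stat5b-CA replicate 1, 72 without replicate 2, 104 without replicate 3 and 141 without replicate 4. With all arrays in the fit it was 15, with array weights 884 and with Y-linked expression as a covariate 474, so the number of genes depends on the model. The difference between the 3′ and 5′ Gapdh probe sets, a sign of RNA integrity, was 0.77 ± 0.53 (SD) in WT and 0.15 ± 0.20 in Stat5b-CA pre-B cells.

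The comparison of Xid with WT pre-B cells asked what the Btk mutation does before any leukemia. It uses the same 5 WT arrays as the comparison of Stat5b-CA pre-B cells, so a difference of the WT group would enter both. Erg, Vpreb1, Hdac9 and Relb moved the same way in both, and neutrophil and myeloid markers in opposite ways. For genes that moved alike, an effect of each genotype cannot be told apart from a difference of the WT group. Btk itself read -0.08 ± 0.13 (SE, n = 3 against 5, adjusted p 0.906, lower on 2 of 3 arrays), and since xid is a point mutation this level checks nothing about the genotype. Cd36, a fatty acid transporter, rose by 1.88 ± 0.19, Erg, an ETS transcription factor, by 1.43 ± 0.25, Enpep, a surface aminopeptidase of early B cells, by 1.18 ± 0.15 and Gfra2, a receptor for glial-derived factors, by 1.16 ± 0.21. Smaller rises were seen for Inka1 by 1.03 ± 0.20, Anxa1 by 1.02 ± 0.23, Sapcd1 by 1.02 ± 0.17, the clotting factor subunit F13a1 by 1.01 ± 0.21, Tmc5 by 0.95 ± 0.09 and Bfsp2 by 0.92 ± 0.20. Among the falls, Cybb, a subunit of the phagocyte oxidase, was lower at -1.95 ± 0.20, the IgM Fc receptor gene Fcmr at -1.91 ± 0.20, Hdac9 at -1.80 ± 0.20, Plek at -1.72 ± 0.17 and Irs1, an adaptor of insulin signalling, at -1.56 ± 0.22. Reln was lower at -2.05 ± 0.30, Myzap at -1.76 ± 0.27, Ms4a6c at -1.52 ± 0.21 and Cldn34c1 at -2.19 ± 0.14. Erdr1 had the largest fall, -4.44 ± 0.30, where its other probe set read -0.62. Adjusted p values of these genes ran from 5.35e-07 for Cldn34c1 to 0.0453 for Anxa1.

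Of 14 immediate-early and stress genes in Xid pre-B cells 1 fell, Egr1, a transcription factor induced by receptor signals, at -1.02 ± 0.15, and 5 were lower adjusted over the list alone, around a median of -0.428 (camera FDR 5.3e-06, adjusted p = 0.552 with an estimated correlation). The NF-kappaB pathway genes had 2 falls among 18, Relb at -0.65 ± 0.14 and the chemokine receptor Ccr7 at -0.70 ± 0.16, and 4 adjusted over the list alone (camera FDR 0.00765, adjusted p = 0.552 with an estimated correlation). Among 18 progenitor and pro-B genes Lmo2 rose by 0.58 ± 0.11 and 3 were higher adjusted over the list alone (camera FDR 0.0128, adjusted p = 0.552 with an estimated correlation). Proliferation genes had 0 of 27 past limma's threshold and a median of 0.0863, with a camera FDR of 0.00765 upward but an adjusted p = 0.923 with an estimated correlation. Neutrophil and myeloid markers likewise had 0 of 18 past the threshold and 4 higher adjusted over the list alone (camera FDR 0.00765, adjusted p = 0.552 with an estimated correlation), with the granule gene Ctsg at 1.36 ± 0.34 on 2 of 3 arrays not passing. The surrogate light chain genes Vpreb1 and Igll1 rose by 0.72 ± 0.11 and 0.91 ± 0.18 while Blk, a Src-family kinase, fell by 0.77 ± 0.13. The most variable Igll1 probe set read -0.04. Il2ra, a STAT5 target that encodes an interleukin 2 receptor chain, was lower at -0.99 ± 0.18 and Pim2 at -0.83 ± 0.19. Pmaip1, a pro-apoptotic gene, was lower at -1.26 ± 0.20, Sdc1 of the plasma cell list at -1.47 ± 0.23 and Cd2 of the T cell list at -1.03 ± 0.16. The name of a list does not show which cells the message came from.

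For Xid against WT pre-B cells limma called 149 of 13256 genes, 39 higher and 110 lower, with 10 and 37 at 2-fold or more and 1422 at an unadjusted p under 0.05. No overlap of groups was seen for 147 of them and for 944 genes in all, 7.12% where chance gives 3.57%. The count was 229 without WT replicate 2, 34 without Xid replicate 1, 397 without Xid replicate 2 and 28 without Xid replicate 3, and 54 with replicate number as a block. With all arrays in the fit it was 7, with array weights 1350, with Y-linked expression as a covariate 56 and with hybridisation controls as a covariate 53. Y-linked genes were detected on Xid replicates 1 and 3 and on WT replicates 2 and 4, and on no other array of these groups. WT replicate 4, described as 1 mouse, had a Y-linked mean of 7.61 beside a value of 13.09 for the sex-linked gene Xist. On Xid replicates 1 and 3 Xist read 8.28 and 8.11, and the reason for this difference was not tested. The 3′ to 5′ Gapdh difference averaged 0.77 ± 0.53 (SD) in WT and 0.25 ± 0.09 in Xid pre-B cells. Hybridisation controls averaged 12.01 in Xid and 11.28 in WT pre-B cells on the log2 scale.

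The comparison of Stat5b-CA leukemia with Stat5b-CA pre-B cells asked what changes when cells of the same genotype become leukemic. Tissue and isolation method differed along with the disease. The 6 leukemia arrays also had the higher deposited medians and lay outside the other leukemia arrays for 453 of 14987 dim probe sets. Disease, tissue, isolation and any separate processing of these arrays cannot be told apart. Stat5b stood at -0.62 ± 0.31 (SE, n = 6 against 4, adjusted p 0.146), a difference that did not pass. Jchain, the joining chain of secreted IgM, rose by 5.05 ± 1.04 (adjusted p 0.000723), Crisp3 by 4.27 ± 0.85, the thioesterase Acot1 by 3.97 ± 0.98, Pcp4, a calmodulin-binding protein, by 3.40 ± 0.71 on 5 of 6 arrays, S100a6, a calcium-binding protein, by 3.39 ± 0.61 and the activation marker Cd83 by 2.94 ± 0.64. Zmat3, a p53 target, rose by 3.28 ± 0.60, Smyd2 by 3.14 ± 0.50, Zdhhc2 by 3.05 ± 0.57 and Gpm6b by 3.01 ± 0.86. Falls included Il2ra at -2.53 ± 0.64, Dntt, the enzyme that adds nucleotides at immunoglobulin gene joints, at -2.48 ± 0.92 (adjusted p 0.0469), the histone gene H3f3b at -3.57 ± 0.49, Cacna2d1, a calcium channel subunit, at -3.28 ± 0.43, Dock8 at -2.85 ± 0.66, Fam117a at -2.66 ± 0.76, F5 at -2.65 ± 0.30, As3mt at -2.62 ± 0.68, Steap4 at -2.54 ± 0.88 and Rps4l at -2.50 ± 0.18. Pax5, a transcription factor that maintains B cell identity, fell by 0.90 ± 0.32 (adjusted p 0.0386).

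MYC-linked biosynthesis genes rose together in Stat5b-CA leukemia, 18 of 21 higher and 0 lower with a median of 0.923, among them Srm, of polyamine synthesis, by 1.75 ± 0.28, Odc1 by 1.05 ± 0.18, the chaperonin Hspe1 by 1.04 ± 0.17 and Fbl, of ribosomal RNA processing, by 0.85 ± 0.15 (20 higher and 1 lower adjusted over the list alone). Camera gave an FDR of 4.52e-09 and an adjusted p = 0.436 with an estimated correlation, and Myc itself rose by 2.25 ± 0.35. Proliferation genes fell, 11 of 27 lower and 0 higher with a median of -0.453, as for Mki67 at -0.76 ± 0.19, Foxm1, a mitotic transcription factor, at -0.55 ± 0.12 and Rrm2 at -0.59 ± 0.15. The camera FDR was 1.91e-07, against an adjusted p = 0.505 with an estimated correlation, with 13 lower adjusted over the list alone. In the pre-B cell receptor list 5 of 21 fell and 2 rose, with Syk, the kinase at its head, at -1.07 ± 0.23, Blk at -2.01 ± 0.56 and Pik3cd at -0.92 ± 0.24 while Bank1, an adaptor, rose by 2.20 ± 0.44. For this list camera gave an FDR of 0.0072 and an adjusted p = 0.436 with an estimated correlation, with 5 lower and 2 higher adjusted over the list alone. NF-kappaB pathway genes showed 5 falls and 1 rise among 18, for example Tnfaip3 and Nfkbia, feedback inhibitors of the pathway, at -0.83 ± 0.20 and -0.84 ± 0.23, against a rise of the adhesion molecule Icam1 by 0.56 ± 0.15 on 5 of 6 arrays. Its camera FDR was 0.0072, against an adjusted p = 0.54 with an estimated correlation, with 6 lower and 2 higher adjusted over the list alone. B cell maturation genes had 5 rises and 0 falls among 23 with a camera FDR of 0.332, including the complement receptor Cr2 by 2.08 ± 0.41 and Fcer2a, the low-affinity IgE receptor, by 1.86 ± 0.55. Some markers of other cells passed without a camera call. Of 19 neutrophil and myeloid markers 6 rose and 13 did not pass, among the rises Lyz1 by 2.30 ± 0.65 and Lyz2 by 1.59 ± 0.55, with 4 of 10 NK cell and cytotoxic markers and 3 of 15 T cell markers. Erythroid markers had 1 rise among 9 and stromal and endothelial markers 4 rises and 2 falls among 11, while plasmacytoid and dendritic cell markers had 0 rises and 1 fall among 10.

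For Stat5b-CA leukemia against pre-B cells limma called 3302 of 14058 genes, 2306 higher and 996 lower, of which 412 and 153 changed by at least 2-fold, and 5097 had an unadjusted p under 0.05. Groups did not overlap for 2371 genes in all, 16.9% where chance gives 0.952%. Leaving out any one array kept the count between 2301 and 3615.

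The 6 leukemia genotypes, weighted equally, were compared with WT pre-B cells to ask what the leukemias share (n = 28 against 5). Tissue and isolation differed here as well. Stat5b rose by 4.00 ± 0.24 (SE, adjusted p 1.26e-14) on 28 of 28 arrays, Socs2 by 3.15 ± 0.22, the STAT5-induced inhibitor Cish by 2.01 ± 0.21 and Myc, a driver of growth and metabolism, by 3.34 ± 0.27. S100a6 rose by 4.27 ± 0.46, Sema4a by 4.23 ± 0.33, Lmo7 by 3.65 ± 0.44, Gimap4, a lymphocyte GTPase, by 3.45 ± 0.37, Kbtbd11 by 3.43 ± 0.24 and Tnfsf11, the cytokine RANKL, by 3.41 ± 0.51. Less uniform were Crhbp by 3.76 ± 0.77 on 24 of 28 arrays, Myl10 by 3.55 ± 0.54 on 27 and Acot1 by 3.47 ± 0.74 on 27. Falls included the adhesion receptor Cd44 at -3.31 ± 0.53, Polm, a polymerase of immunoglobulin gene joining, at -3.04 ± 0.33, the metalloprotease Adam19 at -3.51 ± 0.37, Myzap at -3.63 ± 0.48, H3f3b at -3.60 ± 0.37, Gpr155 at -3.19 ± 0.31, Cacna2d1 at -3.16 ± 0.32 and Fam117a at -2.94 ± 0.57, with Egfl6 at -2.95 ± 0.58 on 27 arrays and the germinal centre gene Fcrla at -2.97 ± 0.76 on 26. Of the genes targeted in this series Prkcb was lower at -1.68 ± 0.21 and Blnk at -1.57 ± 0.28 on all arrays, averages that include the mutant genotypes, Ebf1 at -0.56 ± 0.14 on 23 and Rag2 at -0.89 ± 0.34 on 22. Ebf1 read 1.37 with its most variable probe set, which was dim in WT at 6.43. That probe set averaged 11.10 in the Ebf1+/- leukemias and 6.47 to 7.53 in the other leukemia groups. The remaining, brighter probe sets averaged 11.44, 11.48 and 12.05 in WT. In the leukemia groups they averaged 9.56 to 11.47, 10.01 to 11.43 and 10.47 to 11.65. The rise is thus that of the dim probe set alone.

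B-lineage transcription factors were lower in the leukemias, 13 of 22 with 3 higher and a median of -0.53, as for Bach2, a repressor of plasma cell fate, at -2.10 ± 0.22, Irf4 at -1.43 ± 0.19 and Ikzf1, which encodes Ikaros, at -0.89 ± 0.11. Erg rose in the same list by 1.75 ± 0.21. With camera the FDR was 0.00108 and the adjusted p = 0.369 with an estimated correlation, with 3 higher and 13 lower adjusted over the list alone. NF-kappaB pathway genes had 13 falls and 2 rises among 18, with Relb at -1.58 ± 0.17, Nfkbie at -1.40 ± 0.20 and Tnfaip3 at -1.30 ± 0.15. Camera gave an FDR of 3.19e-05 and an adjusted p = 0.353 with an estimated correlation, with 13 lower and 2 higher adjusted over the list alone. Proliferation genes fell in 18 of 27 cases and rose in 0, Mki67 at -1.05 ± 0.14 and Foxm1 at -0.78 ± 0.09. The camera FDR was 3.75e-06, against an adjusted p = 0.585 with an estimated correlation, with 19 lower adjusted over the list alone. In contrast 20 of 21 MYC-linked biosynthesis genes rose and 0 fell, with a median of 0.981, Nop58, of small nucleolar particles, by 2.38 ± 0.24, Srm by 2.15 ± 0.21 and Ldha, of lactate production, by 1.27 ± 0.13. For this list camera gave an FDR of 4.46e-11 and an adjusted p = 0.353 with an estimated correlation, with 20 higher and 1 lower adjusted over the list alone. NK cell and cytotoxic markers rose in 6 of 10 cases, Klrd1 by 1.92 ± 0.56 on 23 arrays and Ccl5, a chemokine, by 1.21 ± 0.37 on 25. Its camera FDR was 0.0397, against an adjusted p = 0.66 with an estimated correlation, with 8 higher adjusted over the list alone. Of 20 STAT5 target genes 9 rose and 5 fell, Socs2, Cish and Myc among the rises (camera FDR 0.24). Apoptosis and cell-cycle inhibitor genes had 4 rises and 7 falls among 18 (camera FDR 0.627), mitochondrial respiration genes 6 rises among 22 (camera FDR 0.0906) and T cell markers 7 rises among 15 (camera FDR 0.24). Plasma cell markers had 4 rises and 5 falls among 12, with a median of 0.0714, a mean of -0.135 and a test that pointed downward (camera FDR 0.627). None of 3 sex-linked genes passed with limma (camera FDR 0.853). The pre-B cell receptor list split, with 5 rises and 11 falls among 21 (camera FDR 0.0906), Syk at -1.74 ± 0.17 and Igll1 at 1.18 ± 0.14 on 27 arrays, although the most variable Igll1 probe set read -0.29.

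For leukemias against WT pre-B cells limma called 6098 of 14058 genes, 3336 higher and 2762 lower, of which 565 and 429 changed by at least 2-fold, and 7105 had an unadjusted p under 0.05. The groups were fully apart for 631 genes, 4.49% where chance gives 0.000843%. Single omissions kept the count between 5041 and 6273. The 3′ to 5′ Gapdh difference was 0.77 in WT and between -0.13 and 0.13 in the leukemia groups on average.

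Whether the changes made by Stat5b-CA in pre-B cells recur in leukemia was asked from the genes called in both comparisons. Of 13256 genes tested in both, 155 changed the same way, 70 higher and 85 lower, and 3 changed in opposite directions, where independent lists would give 23.2, 24.8 and 48.4. Socs2, Sema4a, Crhbp and Lmo7 were among the genes higher in both. Both comparisons use the WT arrays, which by itself raises the overlap, so the WT arrays were also divided between them. With WT replicates 3 to 5 for the pre-B comparison and 1 and 2 for the leukemias, 77 of 138 genes were shared in direction and 0 were opposite, where independent lists would give 8.69 higher, 6.11 lower and 15.1 opposite. The reverse division gave 74 of 171 and 8 opposite, where independent lists would give 15.1, 14.4 and 29.4. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.525. At an unadjusted p under 0.05 in both, 1410 genes changed the same way and 120 in opposite directions. In 20 simulations of unchanged groups that share the WT arrays the numbers were 122 and 0.2 on average. The simulated lists were smaller, 683 and 466 genes on average against 2339 and 6713 in the data. So 122 is not an expected value for 1410, and the simulations show only that shared arrays favour the same direction. In these simulations the mean r was 0.537, so this r alone shows no relation beyond the shared arrays. With the WT arrays divided r was 0.525 and 0.203. The division does not remove a difference of the WT group as a whole, such as in RNA integrity. The 3′ to 5′ Gapdh difference was 0.90 and 0.22 in WT replicates 1 and 2 and 1.42, 0.23 and 1.04 in replicates 3 to 5. It averaged 0.15 in Stat5b-CA pre-B cells and between -0.13 and 0.13 in the leukemia groups.

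**Figure D2:**
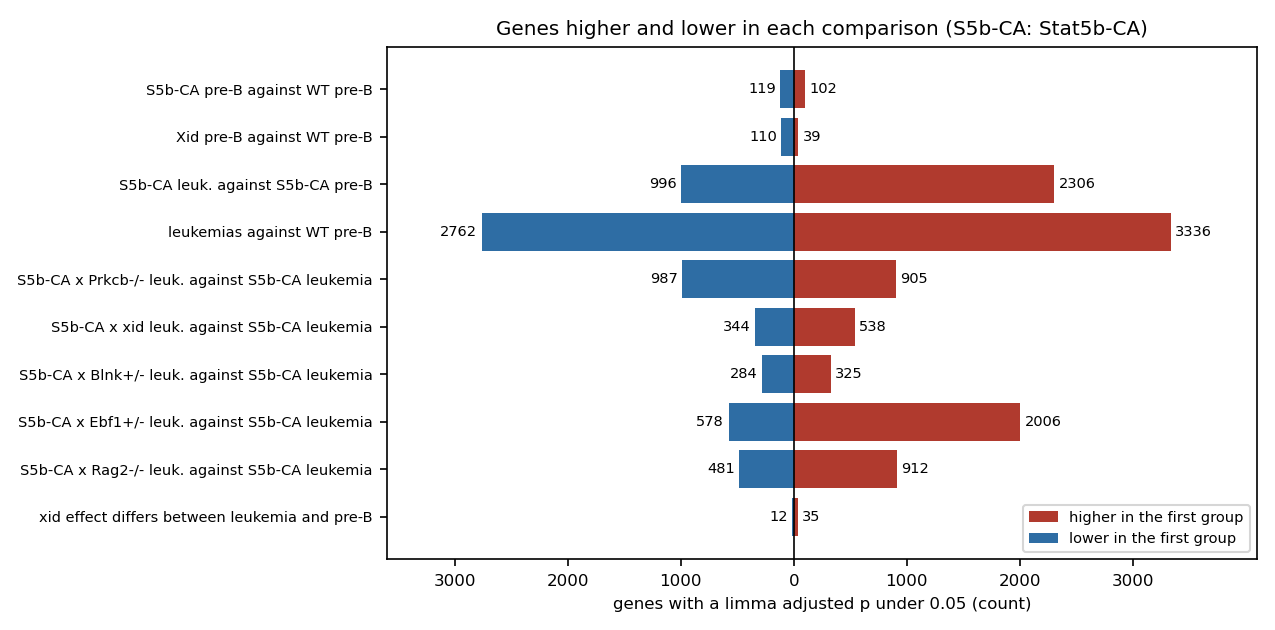
Number of genes with a limma adjusted p under 0.05 (horizontal axis) in each comparison (vertical axis); bars to the right are genes higher and bars to the left genes lower in the first-named group. The leukemias against WT pre-B cells gave 3336 higher and 2762 lower genes, and the difference between the xid effects gave 35 and 12.

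Each second mutation was compared with Stat5b-CA alone to ask whether it changes the expression of the leukemia. The 5 comparisons share the 6 Stat5b-CA leukemia arrays, the ones with the higher deposited medians. Of the genes called, 129 changed the same way in all 5 comparisons, 74 higher and 55 lower in the second mutations, where independent lists would give 0.0082. At an unadjusted p under 0.05 the number was 381, and 20 simulations of unchanged groups that share the 6 arrays gave 7.7 on average and at most 15. The simulated groups held no changes, whereas in the data 2535 to 4757 of 14011 genes passed that threshold per comparison. So 7.7 is not an expected value for 381, and 0.0082 takes no account of the shared arrays.

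In Stat5b-CA x Prkcb-/- leukemia Prkcb fell by 6.26 ± 0.32 (SE, n = 4 against 6, adjusted p 1.96e-12), from 12.58 to 6.32. Another Prkcb probe set averaged 5.94 against 11.31, while a dim one read 6.09 against 6.23. An unchanged 3′ probe set outside the deleted part would have checked nothing. A group of Trim genes, which encode antiviral and ubiquitin ligase proteins, fell with Prkcb. Among them were Trim12a at -5.60 ± 0.29 and Trim30d at -4.26 ± 0.52, and both lie on chromosome 7 as Prkcb does. Jchain was lower at -3.92 ± 0.91 and Tsc22d1, a transcriptional regulator, at -3.98 ± 0.84. The rises were led by Ccn3, a matricellular protein, by 5.03 ± 1.10, Ccnb1ip1 by 3.84 ± 0.56, Pxdn, a peroxidase of the extracellular matrix, by 2.82 ± 0.31, Serpinf1 by 2.59 ± 0.68 and Tmem87a by 2.56 ± 0.34. Ebf1 was lower at -1.14 ± 0.20 (adjusted p 0.000812), with its other probe sets between -0.55 and -0.19, and Bach2 at -1.42 ± 0.34. These and Mef2c, at -0.75 ± 0.22, were the 3 falls among 22 B-lineage transcription factors, with 0 rises. With camera the FDR was 0.0383 and the adjusted p = 0.83 with an estimated correlation, with 4 lower adjusted over the list alone.

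The cytokine receptor and kinase genes of Stat5b-CA x Prkcb-/- leukemia had 5 falls and 0 rises among 21, Jak1 at -0.74 ± 0.16, Stat3 at -0.70 ± 0.15, Stat6 at -0.69 ± 0.18 and Jak2 at -0.46 ± 0.12 among them. Camera gave an FDR of 0.0198 and an adjusted p = 0.83 with an estimated correlation, with 5 lower adjusted over the list alone. NF-kappaB pathway genes fell in 3 of 18 cases, Bcl3 at -1.03 ± 0.33, Relb at -0.86 ± 0.25 and Rela at -0.56 ± 0.15 (3 lower adjusted over the list alone, camera FDR 0.0383, adjusted p = 0.83 with an estimated correlation), and proliferation genes in 4 of 27, Top2a at -0.80 ± 0.20 and Mki67 at -0.77 ± 0.22 among them. The camera FDR was 0.0198, against an adjusted p = 0.83 with an estimated correlation, with 4 lower adjusted over the list alone. None of 16 immediate-early and stress genes passed with limma around a median of -0.428. For this list camera gave an FDR of 0.0198 and an adjusted p = 0.83 with an estimated correlation, with 0 adjusted over the list alone. Against the mean of the other 4 second-mutation genotypes the test of these genes pointed upward relative to the other tested genes. Their median stayed negative at -0.161 (camera FDR 0.916). Erythroid markers had 2 rises among 8, the globin gene Hba-a1 by 0.40 ± 0.10 and Slc4a1 by 0.41 ± 0.10. Its camera FDR was 0.0198, against an adjusted p = 0.406 with an estimated correlation, with 3 higher adjusted over the list alone. The mean of the erythroid list was 7.42 in Stat5b-CA leukemia and between 7.57 and 7.71 in all 5 second-mutation groups. Its rise is thus not particular to Prkcb-/-. Among 11 stromal and endothelial markers the collagen gene Col1a1 rose by 0.43 ± 0.08 and Sparc by 0.25 ± 0.06 while Col6a1 fell by 0.41 ± 0.10. With camera the FDR was 0.0383 and the adjusted p = 0.83 with an estimated correlation, with 5 higher and 1 lower adjusted over the list alone. B cell maturation genes were not called at a camera FDR of 0.0545, with 4 falls among 23 such as Cd83 at -3.12 ± 0.74 and Fcmr at -2.66 ± 0.89. Against the mean of the other 4 second-mutation genotypes Fcmr read 0.07 and Col6a1 0.17, so their falls are relative to Stat5b-CA alone, and Col6a1 fell in all 5 second-mutation comparisons. In all limma called 1892 of 14011 genes, 905 higher and 987 lower, 32 and 135 of them by at least 2-fold, and 4169 had an unadjusted p under 0.05. Groups did not overlap for 1737 genes, 12.4% where chance gives 0.952%. After quantile normalization 1323 were higher and 649 lower, 67.1% higher in place of 47.8%, so the balance of rises and falls is not settled. The count was 1187 without Stat5b-CA replicate 3, 1136 without Prkcb-/- replicate 1 and 1112 without Prkcb-/- replicate 4, and 569 with hybridisation controls as a covariate and 4776 with array weights. In a comparison with the mean of the other 4 second-mutation genotypes, added after the data were seen, 2277 genes were called, 473 higher and 1804 lower (20.8% higher), with 919 shared in direction.

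In Stat5b-CA x xid leukemia Btk read 0.03 ± 0.33 (SE, n = 5 against 6, adjusted p 0.969, higher on 3 of 5 arrays), which checks nothing for a point mutation. Jchain was lower at -4.10 ± 0.86 (adjusted p 0.00484), Lyz1, a lysozyme of myeloid cells, at -2.55 ± 0.66, Cybb at -2.42 ± 0.67, Cldn34c1 at -2.31 ± 0.35 and Cd83 at -2.39 ± 0.69. Ccnb1ip1 rose by 2.24 ± 0.53, Serpinf1 by 2.14 ± 0.64, Msc, a repressor of B cell transcription factors, by 2.02 ± 0.54 on 4 of 5 arrays, Prelid2 by 1.46 ± 0.40 and Agbl5 by 1.41 ± 0.33. The surrogate light chain gene Vpreb1 rose by 0.45 ± 0.08 and the transcription factor Mef2c fell by 0.87 ± 0.20. Immediate-early and stress genes were lower in this genotype, 3 of 16 with a median of -0.741, Egr2 at -0.95 ± 0.26, Ier2 at -0.73 ± 0.19 and Atf3 at -0.52 ± 0.10, and 9 adjusted over the list alone (camera FDR 2.26e-06, adjusted p = 0.334 with an estimated correlation). NF-kappaB pathway genes had 0 of 18 past the threshold with limma and a median of -0.221 (0 adjusted over the list alone, camera FDR 0.0396, adjusted p = 0.597 with an estimated correlation), cytokine receptor and kinase genes 0 of 21 and -0.278 (0 adjusted over the list alone, camera FDR 0.0173, adjusted p = 0.36 with an estimated correlation) and proliferation genes 0 of 27 and 0.161. Camera's FDR came to 0.0388 and an adjusted p = 0.788 with an estimated correlation, with 0 adjusted over the list alone. Among 8 erythroid markers Hba-a1 rose by 0.32 ± 0.09 (2 higher adjusted over the list alone, camera FDR 0.0396, adjusted p = 0.334 with an estimated correlation), and of 11 stromal and endothelial markers 3 rose and 1 fell without a camera call (FDR 0.0638). The mean of the erythroid list was higher than in Stat5b-CA alone in every second-mutation group, so this rise is not particular to xid. Limma called 882 of 14011 genes, 538 higher and 344 lower, 15 and 41 by at least 2-fold, beside 2927 at an unadjusted p under 0.05. No overlap of groups was seen for 758 genes, 5.41% where chance gives 0.433%. The count was 493 without Stat5b-CA replicate 3, 549 without Stat5b-CA replicate 5, 560 without xid replicate 2, 469 without xid replicate 3 and 556 without xid replicate 5. It was 165 with hybridisation controls as a covariate, 245 with a 60th percentile filter and 2146 with array weights. Against the mean of the other 4 second-mutation genotypes, a comparison added after the data were seen, 199 genes were called, 60 higher and 139 lower (30.2% higher in place of 61%), and 67 of them were shared in direction. Serpinf1 read -0.48 and Cd83 0.09 in that comparison. There camera called B-lineage transcription factors upward (median 0.187, FDR 0.0264) and MYC-linked biosynthesis genes downward (median -0.155, FDR 0.0213), each opposite to its uncalled direction against Stat5b-CA alone.

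In Stat5b-CA x Blnk+/- leukemia Blnk fell by 3.84 ± 0.40 (SE, n = 5 against 6, adjusted p 5.03e-06), from 12.98 to 9.14, with array values of 8.81, 8.75, 8.76, 10.76 and 8.60. An unchanged 3′ probe set outside the deleted part would have checked nothing, but this probe set fell. Cd83 was lower at -2.72 ± 0.69, Cd44 at -2.72 ± 0.76, Pcp4 at -3.18 ± 0.77 and Ell2, an elongation factor active in antibody secretion, at -3.12 ± 0.90, although another Ell2 probe set read 0.32. Serpinf1, a secreted serpin, rose by 3.22 ± 0.64, Myl10 by 2.70 ± 0.76, Mc1r, a melanocortin receptor, by 2.04 ± 0.45, Cep170b by 1.57 ± 0.40 and the phosphodiesterase Pde8a by 1.51 ± 0.41. Vpreb1 rose by 0.51 ± 0.08 and Bcl6, a germinal centre repressor, fell by 1.26 ± 0.31. B-lineage transcription factors had 2 falls and 0 rises among 22, Mef2c at -1.0 ± 0.20 and Ets1 at -0.68 ± 0.18. The camera FDR was 0.0068, against an adjusted p = 0.456 with an estimated correlation, with 3 lower adjusted over the list alone. For the B cell maturation genes Cd83 was the 1 fall among 23, with a median of -0.421. For this list camera gave an FDR of 0.0218 and an adjusted p = 0.855 with an estimated correlation, with 1 lower adjusted over the list alone. The direction depended on the reference, since against the mean of the other 4 second-mutation genotypes the test turned upward (median 0.017, FDR 0.71). Of 21 cytokine receptor and kinase genes Stat3 was lower at -0.51 ± 0.14 and Epor at -0.34 ± 0.10. Its camera FDR was 0.0318, against an adjusted p = 0.456 with an estimated correlation, with 4 lower adjusted over the list alone. Immediate-early and stress genes had 1 fall among 16, Atf3 at -0.39 ± 0.10, with a median of -0.399. With camera the FDR was 0.00266 and the adjusted p = 0.456 with an estimated correlation, with 2 lower adjusted over the list alone. Against the other 4 genotypes the test of that list also pointed upward relative to the other tested genes, while its median stayed negative at -0.0356 (camera FDR 0.905). Hba-a1 was the 1 rise among 8 erythroid markers, by 0.33 ± 0.09. Camera's FDR came to 0.044 and an adjusted p = 0.456 with an estimated correlation, with 2 higher adjusted over the list alone. As every second-mutation group had a higher mean of the erythroid list than Stat5b-CA alone, this rise is not particular to Blnk+/-. Limma called 609 of 14011 genes, 325 higher and 284 lower, 9 and 32 by at least 2-fold, beside 2535 at an unadjusted p under 0.05. Groups did not overlap for 651 genes, 4.65% where chance gives 0.433%. The count was 325 without Stat5b-CA replicate 3, 387 without Stat5b-CA replicate 5, 401 without Blnk+/- replicate 2, 396 without Blnk+/- replicate 3 and 369 without Blnk+/- replicate 5. With a 60th percentile filter it was 179, with hybridisation controls as a covariate 199 and with array weights 2872. Against the mean of the other 4 second-mutation genotypes, added after the data were seen, limma called 7 genes, 4 of them shared in direction.

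In Stat5b-CA x Ebf1+/- leukemia Ebf1 read 12.10 against 12.15, a difference of -0.05 ± 0.19 (SE, n = 5 against 6, adjusted p 0.865, lower on 3 of 5 arrays). The direction of Ebf1 depended on the probe set, since another one was higher by 3.60. That other probe set averaged 11.10 here and was dim in every other group, with means between 6.43 and 7.53. Scin, an actin-severing protein, rose by 4.45 ± 0.88 (adjusted p 0.00238), the homeobox gene Dlx1 by 3.80 ± 0.71, Atp8b4, a lipid flippase, by 3.60 ± 0.78, Tnfsf11 by 3.44 ± 0.75 and Emp1 by 3.14 ± 0.67. Kit, the stem cell factor receptor, rose by 3.04 ± 0.75, and Csf2rb2 and Csf2rb, receptor subunits for interleukin 3, by 2.33 ± 0.35 and 2.19 ± 0.59. Falls included Pcp4 at -3.55 ± 0.77, Crisp3 at -3.42 ± 0.94, Eya1 at -3.32 ± 0.64, Reln at -2.55 ± 0.85 and Rsph1 at -2.44 ± 0.53. Eya1 fell in all 5 second-mutation comparisons, so its fall is not particular to Ebf1+/-. Proliferation genes rose in 10 of 27 cases and fell in 0, with Mcm2 and Mcm4 of the replicative helicase at 1.09 ± 0.26 and 0.89 ± 0.21 and Top2a at 0.74 ± 0.19, where the most variable Top2a probe set read -0.04. The camera FDR was 0.00832, against an adjusted p = 0.804 with an estimated correlation, with 13 higher adjusted over the list alone. MYC-linked biosynthesis genes rose in 4 of 21 cases, Tfrc, the transferrin receptor, by 0.71 ± 0.20, Hspd1 by 0.59 ± 0.19, Ncl by 0.46 ± 0.14 and Npm1 by 0.25 ± 0.09. For this list camera gave an FDR of 0.0251 and an adjusted p = 0.804 with an estimated correlation, with 8 higher adjusted over the list alone. Neutrophil and myeloid markers had 3 falls and 1 rise among 17, S100a8 at -2.30 ± 0.63 and the Fc receptor gene Fcgr3 at 1.93 ± 0.39. Its camera FDR was 0.0251, against an adjusted p = 0.804 with an estimated correlation, with 5 lower and 1 higher adjusted over the list alone. B cell maturation genes had Tnfrsf13c, the BAFF receptor, as the 1 fall among 23, at -0.91 ± 0.29. With camera the FDR was 0.0415 and the adjusted p = 0.804 with an estimated correlation, with 0 adjusted over the list alone. Its direction reversed against the mean of the other 4 second-mutation genotypes (median 0.212, FDR 0.778). Without a camera call, 4 of 21 pre-B cell receptor genes rose, Pik3cd by 1.25 ± 0.24, Btk by 1.25 ± 0.33 and Plcg2 by 0.64 ± 0.21 among them, as did Apaf1 and Bcl2l11 of the apoptosis list by 0.92 ± 0.15 and 0.95 ± 0.19 and Stat5a by 0.77 ± 0.18. Limma called 2584 of 14011 genes, 2006 higher and 578 lower, 219 and 66 by at least 2-fold, beside 4757 at an unadjusted p under 0.05. The groups were fully apart for 918 genes, 6.55% where chance gives 0.433%. After quantile normalization 881 were higher and 965 lower, 47.7% higher in place of 77.6%, so the excess of rises is not settled. The count was 1624 without Stat5b-CA replicate 2, 1637 without Stat5b-CA replicate 4 and 1282 without Ebf1+/- replicate 2, and 881 with only the compared groups in the fit. It was 4239 against the mean of the other 4 second-mutation genotypes, 3202 higher and 1037 lower, with 1729 shared in direction.

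In Stat5b-CA x Rag2-/- leukemia Rag2 fell by 2.39 ± 0.57 (SE, n = 3 against 6, adjusted p 0.0112) on 2 of 3 arrays, with values of 7.20, 6.88 and 10.7. The last value belongs to the library labelled Rag2-/- replicate 3 and lies at the level of the other genotypes, where the Stat5b-CA leukemias averaged 10.65. Every direction in this comparison draws in part on that library, without which the count below was 1278. Ifitm1, an interferon-induced membrane protein, rose by 5.86 ± 1.28 (adjusted p 0.00642), Emp1 by 4.21 ± 0.78 and Atp8b4 by 3.97 ± 0.91, with Klhl4 by 4.24 ± 1.13 and Tmed6 by 4.06 ± 1.23 each on 2 of 3 arrays. Enpep was lower at -5.98 ± 1.23, Fcmr at -5.04 ± 0.98, the detoxification enzyme Mgst1 at -4.80 ± 1.10, Cd36 at -4.63 ± 1.22 and Uchl1, a deubiquitinase, at -4.37 ± 1.13. Ighm, the immunoglobulin mu heavy chain gene, was lower at -1.65 ± 0.29, Rag1 at -2.70 ± 0.66 and Vpreb3 at -1.69 ± 0.44. NK cell and cytotoxic markers rose in 7 of 10 cases with a median of 1.48, the granzyme gene Gzma by 3.80 ± 0.59 and the receptor gene Ncr1 by 1.80 ± 0.26 among them. Camera's FDR came to 2.18e-07 and an adjusted p = 0.306 with an estimated correlation, with 9 higher adjusted over the list alone. The mean of this list was 8.611, 10.32 and 8.21 on the 3 arrays and between 7.262 and 7.612 on the Stat5b-CA leukemia arrays. Plasmacytoid and dendritic cell markers rose in 4 of 10 cases, Siglech, a plasmacytoid receptor, by 1.49 ± 0.35 on 2 of 3 arrays. The FDR by camera was 0.00968, against an adjusted p = 0.437 with an estimated correlation, with 6 higher adjusted over the list alone.

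B-lineage transcription factors of the Rag2-/- leukemias had 6 falls and 1 rise among 22, Ikzf3, which encodes Aiolos, at -2.88 ± 0.55, Bach2 at -1.79 ± 0.37, Irf4 at -1.54 ± 0.33 and Lef1 at -2.29 ± 0.49 on 2 of 3 arrays. For this list camera gave an FDR of 0.000271 and an adjusted p = 0.401 with an estimated correlation, with 9 lower and 2 higher adjusted over the list alone. B cell maturation genes fell in 6 of 23 cases, Cd72, a B cell coreceptor, at -2.92 ± 0.55 and Cr2 at -1.94 ± 0.52 beside Fcmr. Its camera FDR was 0.000271, against an adjusted p = 0.724 with an estimated correlation, with 7 lower adjusted over the list alone. MYC-linked biosynthesis genes rose in 4 of 21 cases, Srm by 0.91 ± 0.29 and Tfrc by 0.86 ± 0.23 among them. With camera the FDR was 6.3e-05 and the adjusted p = 0.724 with an estimated correlation, with 10 higher adjusted over the list alone. Of 16 immediate-early and stress genes 2 fell, Egr1 at -2.30 ± 0.63 and Atf3 at -0.45 ± 0.12. Camera's FDR came to 0.0326 and an adjusted p = 0.724 with an estimated correlation, with 3 lower adjusted over the list alone. This list reversed against the mean of the other 4 second-mutation genotypes (median 0.282, FDR 0.739). These falls and rises stood beside the higher NK cell and plasmacytoid markers. Limma called 1393 of 14011 genes, 912 higher and 481 lower, 286 and 177 by at least 2-fold, beside 3779 at an unadjusted p under 0.05. Groups did not overlap for 2178 genes, 15.5% where chance gives 2.38%. After quantile normalization 651 were higher and 533 lower, 55% higher in place of 65.5%. The count was 364 without Rag2-/- replicate 1 and 414 without Rag2-/- replicate 2, and 684 with only the compared groups in the fit.

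**Figure D3:**
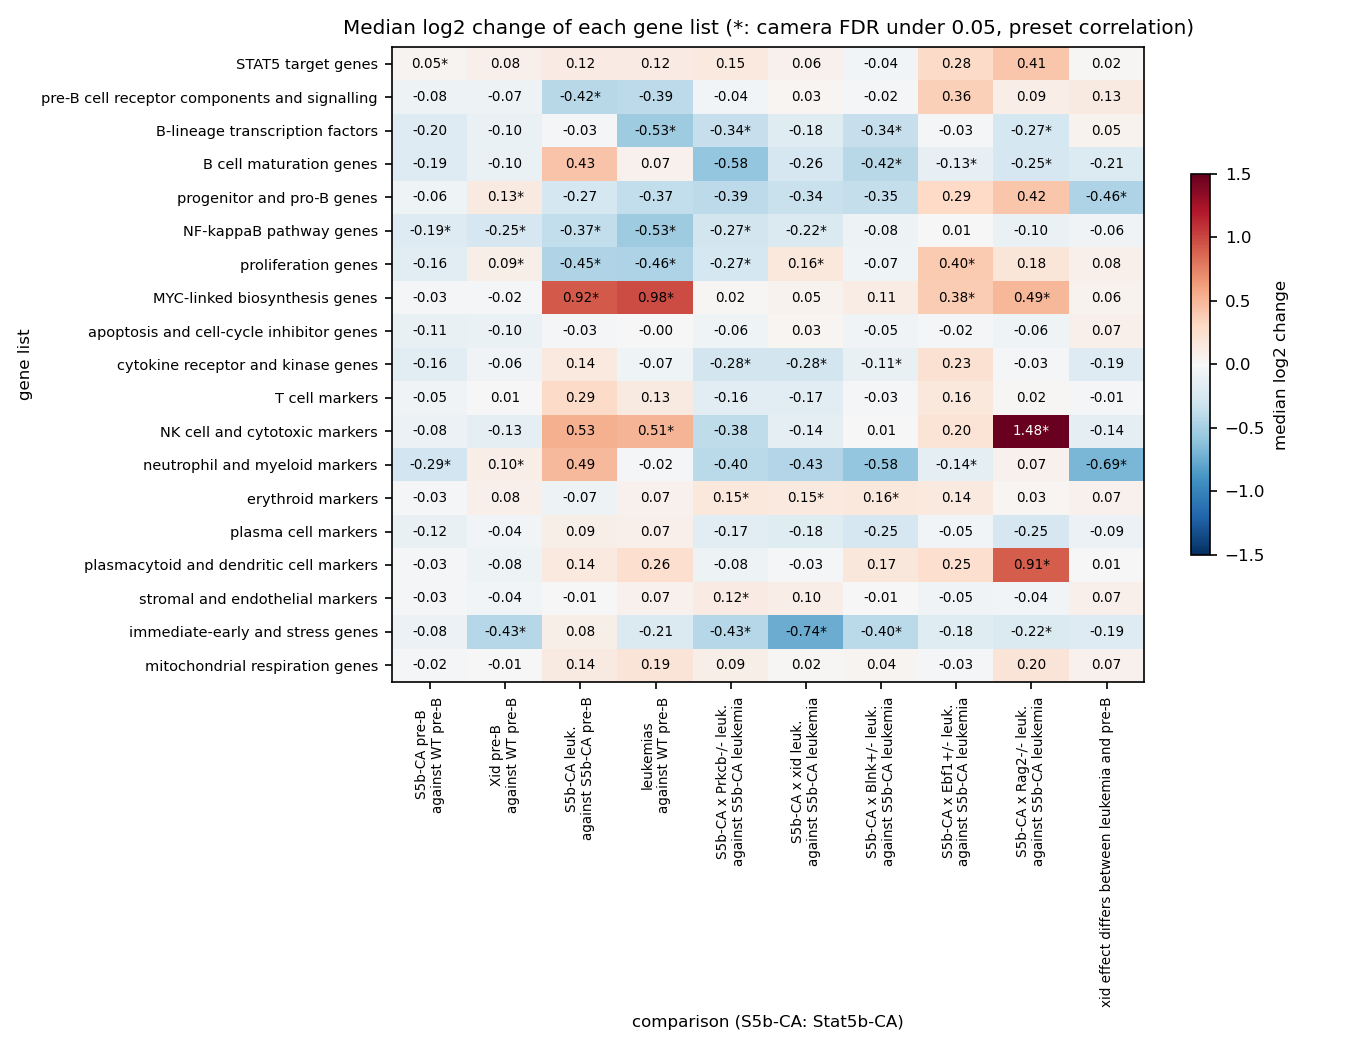
Median log2 change (colour and printed value) of 19 gene lists (vertical axis) in the 10 comparisons (horizontal axis); a star marks a camera FDR under 0.05 with the preset correlation. NK cell and cytotoxic markers had a median of 1.48 in the Rag2-/- leukemias and MYC-linked biosynthesis genes 0.981 in the leukemias against WT pre-B cells.

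The effect of xid was measured in both cell sources, and an interaction contrast asked whether it differs between leukemia and pre-B cells. The xid effect on Actl7a, an actin-related gene, was higher in leukemia by 0.68 ± 0.12 (SE, adjusted p 0.00478), on Gucy1a1, a subunit of the nitric oxide receptor, by 0.60 ± 0.10, on the inflammasome gene Nlrp3 by 0.60 ± 0.14 and on Ocln, a tight junction gene, by 0.59 ± 0.14. Nup98, a nuclear pore gene, read 0.63 in leukemia and -0.22 in pre-B cells, a difference of 0.86 ± 0.20 with an adjusted p of 0.05. The effect was lower in leukemia for Rpl3l at -1.33 ± 0.29, Fbrsl1 at -0.98 ± 0.22, the chromatin protein Cbx3 at -0.77 ± 0.14, Stra6, a retinol transporter, at -0.69 ± 0.13 and Nr1i3, a nuclear receptor, at -0.65 ± 0.12. Of these genes Actl7a, Ocln, Fbrsl1, Cbx3, Stra6 and Nr1i3 changed the same way in all 5 second-mutation comparisons. Their leukemia changes were thus not particular to xid. Of 11 stromal and endothelial markers Col1a1 and Sparc passed at 0.49 ± 0.11 and 0.44 ± 0.09. Progenitor and pro-B genes had 0 of 19 past the threshold with limma and a median difference of -0.458 (1 lower adjusted over the list alone, camera FDR 0.00585, adjusted p = 0.0542 with an estimated correlation), and neutrophil and myeloid markers 0 of 19 and -0.689. The FDR by camera was 3.7e-05, against an adjusted p = 0.248 with an estimated correlation, with 4 lower adjusted over the list alone. Limma called 47 of 14058 genes, 35 higher and 12 lower, beside 1333 at an unadjusted p under 0.05. Of these, 44 were also called with the opposite sign when Stat5b-CA leukemia was set against the mean of the other 5 leukemia genotypes, which uses the same Stat5b-CA and xid arrays. Without a shared leukemia array, the interaction was called with 3 Stat5b-CA arrays and the other 3 were set against the 4 genotypes other than xid. Over the 20 such divisions, which overlap, 360 of 630 calls (57.1%) were called there with the opposite sign and 2 with the same sign, where 2.77% of all genes were called on average. The count was 30 without WT replicate 1 and without WT replicate 3, 29 without WT replicate 4, 25 without Xid replicate 1 and 14 without Xid replicate 3. It was 31 without Stat5b-CA replicate 2 and without xid leukemia replicate 3, and 29 without Stat5b-CA replicates 3 or 5 or xid leukemia replicate 5. A 60th percentile filter left 2 genes, no filter gave 264 and array weights 897.

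The xid effects in pre-B cells and in leukemia share no arrays, so the genes called in both were counted. Of 13209 genes tested in both, 12 fell and 1 rose in both sources and 0 changed in opposite directions, where independent lists would give 2.39, 1.43 and 4.77. Vpreb1 was the gene that rose. Those that fell included Cybb, Cldn34c1, Irs1, the phosphatase gene Dusp5, Tirap, an adaptor of Toll-like receptors, and Hivep1, names chosen after their values were seen. The leukemia changes rest on the Stat5b-CA leukemia arrays as reference, and against the mean of the other 4 second-mutation genotypes 4 of the 13 passed, Atp6ap1, Chm, Cldn34c1 and Dusp5. There Vpreb1 read 0.10 (adjusted p 0.43), Irs1 0.0052 (adjusted p 0.994) and Tirap -0.21 (adjusted p 0.627), so these leukemia changes were not shown to be particular to xid. Cybb and Hivep1 kept their direction and missed the threshold (adjusted p 0.063 and 0.052). Of the 13 genes 4 lie on chromosome X with Btk, namely Atp6ap1, Chm, Cldn34c1 and Cybb, the chromosome of 2.95% of tested genes.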

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

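The tests of separate processing, of the hybridisation controls, of a chromosome segment, of interferon-driven genes and of 1 Blnk allele, and the division of the Stat5b-CA leukemia arrays, were chosen after the results they address were seen.

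In the Stat5b-CA x Blnk+/- leukemias, replicate 4 had a Blnk value of 10.76 where the other arrays lay between 8.60 and 8.81, and a Prkcb value of 10.31 against 12.23 to 12.72. The group mean was itself far below that of Stat5b-CA leukemia, and several explanations were weighed. Loss of the message of 1 allele would halve the level, whereas the 95% interval ran from -4.68 to -3.01 and its upper bound of -3.01 argues against that as the whole cause. Fewer B-lineage cells were argued against by the other 20 members of the pre-B cell receptor list, whose median change was 0.0187 with an SD of 0.394. Loss or silencing of the other allele in the tumours and a genotype other than the label states may explain the level, and neither was tested.

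The 6 Stat5b-CA leukemia arrays are the shared reference of the 5 second-mutation comparisons, in all of which 129 genes changed the same way. Separate processing of these arrays is a candidate explanation, since they lay outside the other 22 leukemia arrays for 453 of 14987 dim probe sets, 231 higher and 222 lower, against a highest of 1 in 100 random sets of 6 arrays. The other genotypes gave between 1 and 32. With the level of the hybridisation controls as a covariate, 0.966 of the median absolute change of these 129 genes was kept (0.389 of 0.403). That argues against this level for these genes only, since selection for a shared direction leaves out genes that follow the controls. The controls averaged 10.73 in Rag2-/-, 11.11 in Stat5b-CA leukemia and 11.69 to 11.80 in Prkcb-/-, xid and Blnk+/-. With the covariate the counts were 569 for Prkcb-/-, 165 for xid, 199 for Blnk+/-, 874 for Rag2-/- and 3184 for Ebf1+/-. Absence of a second mutation, the biological difference the design names, stays open and is confounded with the processing. The same 6 arrays enter the comparison with Stat5b-CA pre-B cells, so its 3302 genes are open to separate processing too, beside disease, tissue and isolation.

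In Stat5b-CA x Prkcb-/- leukemia 5 neighbouring Trim genes fell, with Trim34a at -3.21, Trim5 at -3.58, Trim12a at -5.60, Trim30a at -1.68 and Trim30d at -4.26 on the log2 scale. Trim12c, which lies between Trim12a and Trim30a, did not pass at -0.38 (adjusted p 0.402), nor did Trim6, next to Trim34a, at -0.0014 (adjusted p 0.992). A chromosome segment of another strain carried along with the targeted gene, 110 to 115 tested genes away, stays open. Such a segment would take in the 109 tested genes between them, of which 0 changed at least 2-fold, against a median of 1 and a highest of 7 in windows of as many genes elsewhere. Of these genes 17 passed the threshold, against a median of 15, so this test decided neither way. Lower interferon-driven transcription was argued against as the whole cause for Trim34a, Trim5, Trim12a and Trim30d. The 27 other interferon-driven genes had a median of -0.836 with quartiles of -1.18 and -0.408, and 6 fell and 0 rose with limma. All 27 read negative, where the median of all tested genes was -0.0387, so a smaller fall of such genes stays open. Trim30a lay within their range, of which the lowest was Xaf1 at -2.30, so the argument does not cover Trim30a. Joint regulation of this gene family and an effect of Prkcb on it were not tested.

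Chance gives about 1 in 20 groups with an array this far from the rest, and 15 of 196 groups (7.65%) had one. WT pre-B replicate 3 had low values of Stat5a, 8.72 against 9.15 to 9.26, and of Btk, 11.54 against 12 to 12.12. Ebf1+/- replicate 2 had a low Prkcb value of 12.01 against 12.72 to 12.97. Prkcb-/- replicate 2 had a low mean of B-lineage transcription factors, 10.92 against 11.25 to 11.29, and a high mean of plasmacytoid and dendritic cell markers, 8.25 against 7.85 to 7.88. Stat5b-CA pre-B replicate 1 had a high mean of progenitor and pro-B genes, 11.02, and low means of T cell markers, 7.58 against 7.83 to 7.86, and of plasmacytoid and dendritic cell markers, 7.72 against 7.94 to 7.97. Stat5b-CA leukemia replicate 6 had a low mean of proliferation genes, 11.09 against 11.58 to 11.79, and xid leukemia replicate 4 a high mean of NK cell and cytotoxic markers, 7.74 against 6.77 to 6.99. Blnk+/- replicate 3 had a high mean of immediate-early and stress genes, 9.82 against 8.82 to 8.91. Hybridisation controls were low on Blnk+/- replicate 1, 11.51 against 11.81 to 11.86, and high on Ebf1+/- replicate 5, 12.1 against 10.98 to 11.29.

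The xid effect differed between leukemia and pre-B cells for 47 genes, for progenitor and pro-B genes by a median of -0.458 and for neutrophil and myeloid markers by a median of -0.689. Neither list difference holds with an estimated correlation (adjusted p = 0.0542 and 0.248), and 0 of 19 members passed with limma in each list. Of the 47 genes 44 also set Stat5b-CA leukemia apart from the other leukemias with the opposite sign, a count raised by the shared arrays. With no leukemia array shared, 57.1% of the calls over 20 divisions did so, where 2.77% of all genes were called. Probe sets without a gene name, not used in the comparisons, gave 4 changes among 4004 tested in Stat5b-CA against WT pre-B cells and 1765 among 4337 in the leukemias, 478 higher and 1287 lower.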

How the results depend on the processing

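The comparisons with the other 4 genotypes, with hybridisation controls and without the library labelled Rag2-/- replicate 3 were chosen after the data were seen. Of the counts recomputed in ways other than omitting a single replicate 108 stayed within 1.5 times and 47 did not, and the cause was not tested unless stated. Without a filter the count was 132 for Stat5b-CA and 63 for Xid pre-B cells, 2853 for Prkcb-/-, 1907 for xid, 1547 for Blnk+/- and 264 for the interaction. A 60th percentile filter, which tests fewer genes, gave 1175 for Prkcb-/-, 245 for xid, 179 for Blnk+/- and 2 for the interaction. With all arrays in the fit the pre-B counts were 15 for Stat5b-CA and 7 for Xid. With only the compared groups they were 488 for xid, 378 for Blnk+/-, 881 for Ebf1+/-, 684 for Rag2-/- and 27 for the interaction. Array weights gave 884 for Stat5b-CA and 1350 for Xid pre-B cells, 5571 for Stat5b-CA leukemia against pre-B cells, 4776 for Prkcb-/-, 2146 for xid, 2872 for Blnk+/-, 2308 for Rag2-/- and 897 for the interaction. Y-linked expression as a covariate gave 474 for Stat5b-CA and 56 for Xid pre-B cells and 29 for the interaction. The mean of probe sets gave 23 and eBayes without trend 30 for the interaction, and Stat5b-CA pre-B cells without pooled arrays gave 138. Hybridisation controls as a covariate gave 53 for Xid pre-B cells, 569 for Prkcb-/-, 165 for xid, 199 for Blnk+/- and 874 for Rag2-/-. Against the mean of the other 4 genotypes the counts were 199 for xid, 7 for Blnk+/- and 4239 for Ebf1+/-. The overlap of 155 became 34 with a change of at least 1 in both and 77 or 74 with the WT arrays divided, where fewer arrays were used. Of 46 list calls 0 held with an estimated correlation.

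The replicate block gave 54 genes for Xid pre-B cells, 1493 for Ebf1+/-, 896 for Rag2-/- and 30 list calls. The replicate numbers do not pair the samples: 7 of 40 arrays correlated best with an array of their own number, and pairs of the same number had a mean r of -0.0105 against 0.00365 for other pairs, which is at most a hint from the data.

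Omitting single replicates gave ranges of 72 to 484 for Stat5b-CA and 28 to 397 for Xid pre-B cells, 2301 to 3615 for Stat5b-CA leukemia against pre-B cells and 5041 to 6273 for the leukemias. The ranges were 1112 to 2350 for Prkcb-/-, 469 to 1022 for xid, 325 to 730 for Blnk+/-, 1282 to 3140 for Ebf1+/-, 364 to 1873 for Rag2-/-, 14 to 66 for the interaction and 30 to 56 for list calls. Of these counts 131 stayed within 1.5 times and 40 did not.

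Directions reversed for 13 gene values that passed in the main fit or in the alternative. With the most variable probe set Ebf1 read 1.37 in the leukemias and 3.60 in Ebf1+/-, Igll1 -0.037 in Xid pre-B cells and -0.29 in the leukemias, and Top2a -0.038 in Ebf1+/-, and with the mean of probe sets Ebf1 read 0.57 in Ebf1+/-, since the probe sets differ. Against the other 4 genotypes Prkcb read 1.66 in xid and 1.51 in Rag2-/-, a comparison that includes Prkcb-/-, Ebf1 0.66 in Ebf1+/-, Col6a1 0.17 and Fcmr 0.068 in Prkcb-/-, and Serpinf1 -0.48 and Cd83 0.093 in xid. In that comparison 7 list tests that were called with either reference also changed direction relative to the other tested genes. Immediate-early genes had medians that stayed negative in Prkcb-/- and Blnk+/-, at -0.161 and -0.0356, and a median of 0.282 in Rag2-/-. Maturation genes had medians of 0.017 in Blnk+/- and 0.212 in Ebf1+/-. In xid B-lineage transcription factors had a median of 0.187 and MYC-linked genes -0.155, and camera called both against this reference (FDR 0.0264 and 0.0213). Of the other gene values under these alternatives 4298 kept their side of the threshold, 507 no longer passed and 19 newly passed. With single replicates omitted the numbers were 3953, 437 and 4. List tests gave 851, 92 and 30, and with omissions 2495, 70 and 55. Intensities near the floor of 16 carry little signal over background, so changes of dim genes are the least certain.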

Other observations

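All splits of the arrays and the test of fewer B-lineage cells were planned; the counts of shared xid genes by chromosome, and the marker levels of single Rag2-/- libraries, were chosen after the results were seen.

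Between Stat5b-CA and WT pre-B cells 221 genes were called, with Socs2, a feedback inhibitor of STAT5, and cyclin D2 among the rises, and 155 of them moved the same way in the leukemias. Both comparisons share the WT arrays, and with these divided 77 of 138 moved the same way and 0 the opposite, or 74 of 171 and 8. The division does not remove a difference in RNA integrity between WT and the other groups. In the leukemias 20 of 21 MYC-linked biosynthesis genes rose, while 18 of 27 proliferation genes fell and 9 did not pass. Of 22 B-lineage transcription factors 13 fell and 3 rose, and of 18 NF-kappaB pathway genes 13 fell and 2 rose. None of these list calls holds with an estimated correlation. In the same comparison 6 of 10 NK cell and cytotoxic markers and 7 of 15 T cell markers rose, and the 3′ to 5′ Gapdh difference was 0.77 in WT and between -0.13 and 0.13 in the leukemia groups. Tissue and isolation cannot be told apart from disease there.

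For Stat5b-CA pre-B cells 2 of 100 splits of the same arrays, the real one included, gave as many genes as the real 221, the highest other being 353 with WT replicate 5 set beside Stat5b-CA replicates 2, 3 and 4. For Xid pre-B cells 2 of 56 splits reached 149, the highest other being 373 with WT replicates 1 and 2 and Xid replicate 2 together. Both shares lie under 0.05, but a split that crosses the genotypes gave more genes than the real one in each, which points to a structure of the arrays beside the genotype, so these 2 counts cannot be ascribed to genotype alone. In the other comparisons the real split alone, 1 of 100, reached its count, so chance alone is an unlikely source. The splits cannot tell genotype from separate processing where the Stat5b-CA leukemia arrays form a side, as in the second-mutation comparisons. Against the mean of the other 4 genotypes limma called 7 genes for Blnk+/-. The real and highest other counts were 3302 and 2734 for Stat5b-CA leukemia against pre-B cells, 6098 and 45 for the leukemias, 1892 and 860 for Prkcb-/-, 882 and 315 for xid, 609 and 305 for Blnk+/-, 2584 and 1640 for Ebf1+/-, and 47 and 4 for the interaction. For Rag2-/- it was 1 of 84, with 1393 and 1166.

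The library labelled Rag2-/- replicate 3 kept a Rag2 value of 10.7 and was the lowest of its group for NK cell and cytotoxic markers, at 8.21. Without it the median of these markers was 2.04, and that of plasmacytoid and dendritic cell markers 1.14. Bead selection for B220 and CD19 would remove cells that carry neither, and no share of other cells was estimated.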
